A study of Mus musculus with 20 samples.

How the data were processed

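The series holds 20 CUT&Tag libraries of mouse ganglia labelled CVG at embryonic day 11.5. Groups were taken from the sample titles: ISL1_26 (1 library), ISL1_70 (3), POU4F1 (2), H3K4me3 (2), H3K27me3 (3), H3K27ac (3), IgGR (3) and IgGM (3). The antibody label is ISL1 for both ISL1 groups, and their 4 libraries were treated as replicates of 1 target. No peak list of the 6 IgG libraries was used here.

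The authors' peak lists used here are 1 for each of 14 libraries, without pooling of replicates. Per the file headers (the names of the peaks), peaks were called with MACS2 against a control, and the control library and options are not given in the sources used here. Per the submitters' processing notes, FastQC, Bowtie2 and SEACR were also used, with the genome build mm10; their versions and roles are not given. The deposited columns hold the fold enrichment of each peak, a ratio to the caller's local background, and the −log10 of its p-value and q-value, as the authors' peak caller gave them, together with the summit position. Every list ends at a −log10 q of 1 (q of 0.1). These values were used to rank or filter peaks within a list and, for H3K27me3 replicate 1 and the POU4F1 libraries, to set the median of a list against a cutoff. They were not compared between lists, since lists from libraries of unknown depth are not comparable in fold or q. A deeper library or a looser background gives more peaks, which changes every count of regions and every overlap.

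Peaks on chromosomes 1 to 19, X and Y were kept. Peaks of a target that overlapped by at least 1 bp were merged, and a merged region with a peak in at least 2 libraries of the target was called replicated. Factor regions were classed as shared, ISL1 only or POU4F1 only from the union of replicated regions. An ISL1 only or POU4F1 only region lacks a replicated region of the other factor but can hold unreplicated peaks of it. Overlap was tested against circular shifts, with a random offset per chromosome: 1000 shifts for replicated regions and 200 for pairs of libraries, one-sided. Association within H3K27ac regions was tested with the Mantel-Haenszel method over 10 deciles of region width. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 9 mark comparisons; Wilson intervals are at 95% and cover counting error only. No test treats libraries as replicates of a measured level, so p-values over regions or genes describe these lists and not the spread between embryos.

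Genes came from a RefSeq table of assembly GRCm38.p6, whose primary chromosomes are those of mm10; 21887 protein-coding genes were used. The table gives gene starts and ends without strand, transcripts, exons or UTRs. Promoters planned as TSS windows were therefore replaced by windows of 1 kb around either end of a gene, and the planned 10 kb upstream by the gene body with 10 kb on each side. The windows therefore hold 3′ ends as well as promoters, and the nearest gene is the one with the nearest end. An alternative planned as summits within 200 bp is the same as overlap of windows of 100 bp each side of the summits and was run once. With no genome sequence at hand, the planned motif test at summits was not run.

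The 12 gene lists (261 genes, of which 261 matched the table) and the rule for named genes were fixed before the data were examined. The number of members with a feature was compared with 10000 random lists matched on gene length in 20 bins, one-sided, adjusted over the 12 lists; the smallest p is 1e-04. Lists covered inner ear neuron transcription factors, neurotrophin and survival signalling, axon guidance and adhesion, neuronal cytoskeleton and synapse, Schwann cell and neural crest, otic epithelium and hair cells, mesenchyme, endothelium and blood, muscle, heart, gut and liver, Hox, cell cycle and progenitors, and housekeeping. By the rule, Isl1 and Pou4f1 come first, then up to 4 members per list with a shared region, ranked by the mean percentile of their best peak over the 6 factor libraries, up to 2 members of lists marked by H3K27me3, ranked by the number of libraries with H3K27me3 at a gene end and then by covered length, the 10 leading shared and 5 leading single-factor regions, and the 5 genes outside the lists with the largest H3K27me3 length and with the most shared regions. Because a single list member had a shared region, the same rank over the 4 ISL1 libraries was used for members with an ISL1 region, an addition made after the data were examined. So were the counts of ISL1 regions per list, the counts with POU4F1 replicate 1 alone, the match on H3K27ac, the counts of genes with both marks, their leave-outs and their expectation from the single marks, the one-sided test for fewer members and the split by the number of ISL1 libraries. Members of the POU4F1 replicate 1 and H3K27ac counts that are named as examples were chosen after their values were seen. Values of some single genes are not reported.

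The tests were run on simulated data first. With 500 regions and none planted on the other set, the shift test called 4% of 50 runs, and with 100 of 500 planted the excess over the shifted number was 99.6% of those planted. The unplanted regions were placed at random along the chromosomes. The 4% therefore does not carry over to peak lists, which can favour the same parts of the genome whatever the target. With 50000 regions and marks that both followed width, the Mantel-Haenszel estimate averaged 1.01 for a true odds ratio of 1 and 3.00 for a true odds ratio of 3. With 21887 genes, the list test called 4% of 50 unenriched lists and 100% of lists with 15 of 30 members planted. In the Mantel-Haenszel and list simulations, mark rates were set by deciles of width or length that the tests themselves adjust for. They therefore do not show how the tests behave where marks vary with width or length within a bin, or with other properties. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

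Alternatives were a −log10 q of at least 5, the 10000 best peaks per library, regions of any or of every library, an overlap of 50% of the shorter region, windows of 100 bp each side of the summit, windows of 5 kb, other links of regions to genes, H3K4me3 in place of H3K27ac regions, and leaving out each library. Added later were leaving out 3 libraries together (POU4F1 replicate 2, the library labelled H3K4me3 replicate 1 and H3K27me3 replicate 1) and leaving out regions called in 12 or more of the 14 libraries.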

Results

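CUT&Tag, in which an antibody guides a transposase to a chromatin protein or a histone modification so that the DNA beside it is released and sequenced, was applied to ganglia of C57BL/6J mouse embryos at E11.5 (the embryonic day). The tissue is labelled CVG, an abbreviation used in inner ear work for the cochleovestibular ganglion, from which the auditory and vestibular neurons arise. The targets were ISL1, a LIM homeodomain transcription factor, POU4F1, a POU homeodomain transcription factor, and the histone modifications H3K4me3, H3K27ac and H3K27me3, which mark promoters, active promoters and enhancers, and Polycomb-repressed chromatin. The series title names the question, whether the ISL1 and POU4F1 proteins interact in controlling how sensory neurons of the inner ear develop and survive. Of the 20 samples, 14 had a peak list: 4 ISL1 libraries in the groups ISL1_26 (n = 1) and ISL1_70 (n = 3), 2 of POU4F1, 2 of H3K4me3, 3 of H3K27me3 and 3 of H3K27ac. The 6 IgG libraries were not analysed here. The labels do not say what 26 and 70 stand for, nor whether the libraries of a group came from separate embryos or dissections, so agreement between replicates may be technical. Read totals are not in the lists, and the depth behind each list is unknown.

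ISL1 lists were on average longer than POU4F1 lists, at 60563 ± 33053 peaks (SD, n = 4) against 31673 ± 3644 (SD, n = 2), and H3K27ac had the widest spread between libraries, from 8855 to 168144. On chromosomes 1 to 19, X and Y, the ISL1_26 list held 95719 peaks, and the ISL1_70 lists held 80293, 24573 and 41668. The POU4F1 lists held 34249 and 29096 peaks, the H3K4me3 lists 15785 and 22425, the H3K27me3 lists 19243, 14140 and 39310, and the H3K27ac lists 8855, 106628 and 168144. Factor peaks were narrow, with medians from 455 to 478 bp. The longest peaks belonged to H3K27me3 replicate 3 (88.3 kb), H3K27me3 replicate 2 (87.7 kb) and the library labelled H3K4me3 replicate 1 (87.9 kb), whereas the longest peak of H3K4me3 replicate 2 was 7.53 kb. Peaks within 1 kb of either annotated end of a protein-coding gene made up 52.3%, 13.3% and 9.49% of H3K27ac replicates 1 to 3, 36.1% of H3K4me3 replicate 2 and 5.69% to 8.85% of the 6 factor lists.

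After peaks of a target were merged across its libraries, 20413 of 214116 ISL1 regions (9.53%) had a peak in at least 2 libraries, and 1547 of them in all 4. For POU4F1, 545 of 62799 regions (0.868%) were present in both libraries. The corresponding replicated sets held 2039 of 35862 H3K4me3 regions, 11078 of 52503 H3K27me3 regions and 49941 of 220803 H3K27ac regions. Replicated H3K4me3 regions lay within 1 kb of a gene end in 73.3% of cases, H3K27me3 regions in 41.0%, H3K27ac regions in 21.0%, POU4F1 regions in 18.0% and ISL1 regions in 14.8%. Leaving out a library moved several of these counts by more than 1.5 times: without ISL1_26 replicate 1 the ISL1 set held 8418 regions and without ISL1_70 replicate 1 it held 9623. Without H3K27ac replicate 2 or 3 the H3K27ac set held 5044 or 5197 regions, and without H3K27me3 replicate 2 or 3 the H3K27me3 set held 3969 or 3440. With a single library left, the POU4F1 set is that library's own list of 29096 or 34249 peaks and the H3K4me3 set 22425 or 15785.

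ISL1 libraries overlapped one another and H3K27ac libraries, the POU4F1 libraries overlapped each other little, and a library labelled H3K4me3 resembled H3K27me3. The 6 pairs of ISL1 libraries shared 3.86 to 5.97 times as many peaks as after circular shifts of the shorter list, with 3.86 to 4.96 for ISL1_26 with ISL1_70 and 4.07 to 5.97 within ISL1_70. This was not particular to the target: pairs of an ISL1 with an H3K27ac library stood at 2.96 to 7.43, and by Jaccard index 3 of the 4 ISL1 libraries were closest to H3K27ac replicate 2 (0.0386 to 0.0892). The 2 POU4F1 libraries shared 1.87% of the shorter list against 1.28% after shifts, a ratio of 1.46. Every one of the 91 library pairs, whatever the targets, lay above 1 with a permutation p of 0.00498, the smallest that 200 shifts could give. The library labelled H3K4me3 replicate 1 had a Jaccard index of covered bases of 0.742 with H3K27me3 replicate 2 and 0.496 with H3K27me3 replicate 3, but 0.036 with H3K4me3 replicate 2. It had peaks at gene ends of 20 of 20 Hox genes, the classical Polycomb targets, and of 0 of 20 housekeeping genes, while H3K4me3 replicate 2 had peaks at 5 and 17 of them. H3K27me3 replicate 1 was mixed, with 16 Hox and 9 housekeeping genes and 22.0 times the shifted overlap with H3K4me3 replicate 2 and 32.8 times with H3K27ac replicate 1, against 15.5 and 12.4 times with H3K27me3 replicates 2 and 3. Its peaks lay near the calling threshold, with a median −log10 q of 1.09 against the cutoff of 1.

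**Figure D1:**
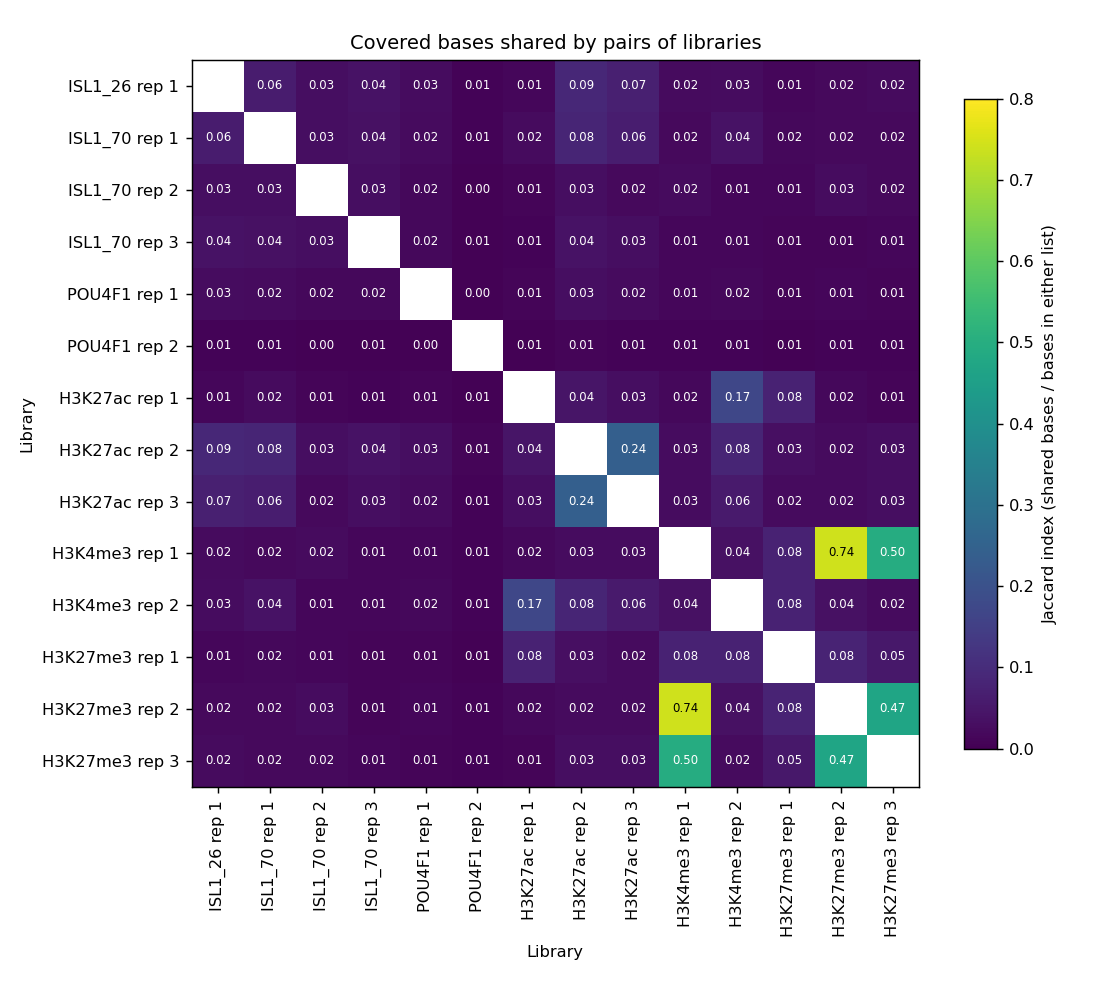
Jaccard index of covered bases (colour scale 0 to 0.8, no unit) for each pair of the 14 libraries on both axes, the diagonal left blank. The library labelled H3K4me3 replicate 1 stands at 0.742 with H3K27me3 replicate 2, the highest value of any pair, and the POU4F1 libraries stand at 0.00463 with each other.

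ISL1 and POU4F1 were found at the same places more often than shifted positions allowed. Of the 545 replicated POU4F1 regions, 101 (18.5%) overlapped a replicated ISL1 region, against 8.0 ± 2.78 (SD) in 1000 circular shifts, 12.6 times as many (one-sided permutation p = 0.000999, the smallest the shifts could give). All 8 pairs of a single ISL1 with a single POU4F1 library also exceeded their shifts, with ratios of 3.29 to 4.66 for POU4F1 replicate 1 and 1.51 to 1.77 for POU4F1 replicate 2. The ratio between the POU4F1 libraries themselves was 1.46. An excess of this size was not particular to ISL1. With the histone libraries, POU4F1 replicate 1 stood at 2.03 to 4.86 and POU4F1 replicate 2 at 1.61 to 3.16. With POU4F1 replicate 1 alone, 3014 peaks overlapped a replicated ISL1 region, 7.29 times the shifted number, and with replicate 2 alone, 710 peaks did so, 2.13 times the shifted number. Without ISL1_26 replicate 1 the overlap was 63 regions, 19.2 times the shifted number.

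The share of ISL1 regions with a POU4F1 replicate 1 peak rose with the number of ISL1 libraries that called the region. It was 10.6% (95% Wilson interval 10.1 to 11.1) of the 15245 regions called in 2 ISL1 libraries, 21.6% (20.3 to 23.0) of the 3621 called in 3 and 34.5% (32.1 to 36.9) of the 1547 called in 4. For POU4F1 replicate 2 the shares were 3.04%, 4.42% and 5.56%. Regions called more often were also wider, with medians of 791, 1183 and 1589 bp, but the order held for POU4F1 replicate 1 in windows of 100 bp each side of the ISL1 summit, at 7.06%, 13.6% and 23.6%. It did not hold there for POU4F1 replicate 2, at 1.71%, 2.27% and 2.20%. H3K27ac followed the same order, at 40.1%, 66.1% and 77.9% of regions. This split by library number was chosen after the data were examined.

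**Figure D2:**
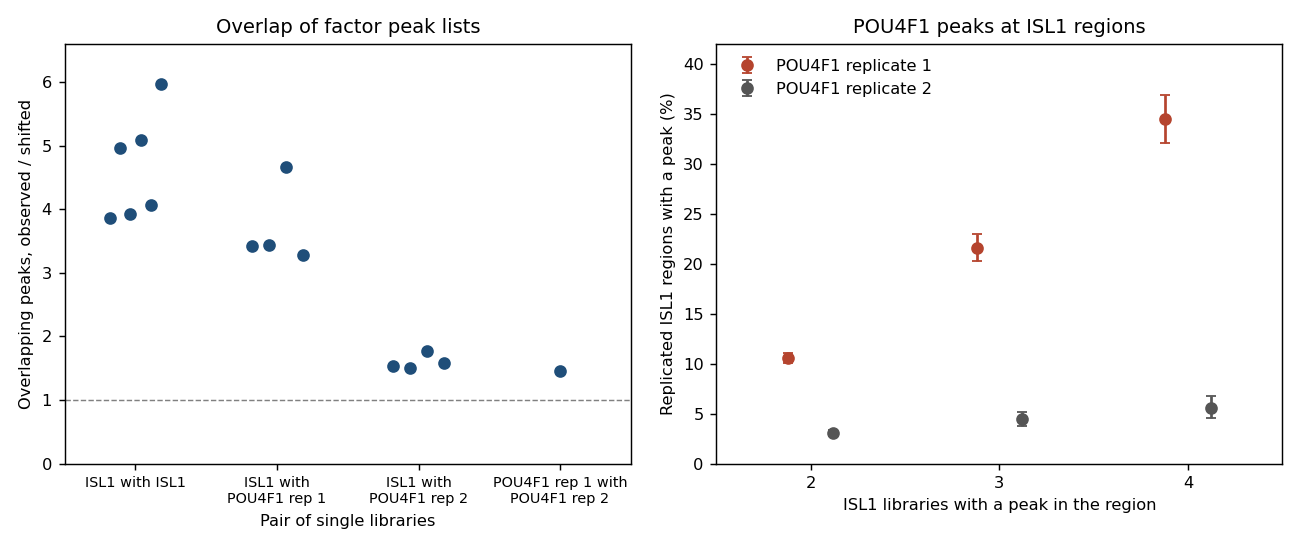
Left, observed over shifted number of overlapping peaks for pairs of single libraries, each point a pair and the dashed line 1; right, replicated ISL1 regions with a peak of POU4F1 replicate 1 or 2 (%), by the number of ISL1 libraries that called the region, with 95% Wilson intervals. Pairs of ISL1 with POU4F1 replicate 1 lie at 3.29 to 4.66 and pairs with replicate 2 at 1.51 to 1.77, and the share with POU4F1 replicate 1 goes from 10.6% to 34.5%.

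The association was also measured among H3K27ac regions alone. Of 49941 replicated H3K27ac regions, 9457 overlapped an ISL1 region, 192 a POU4F1 region and 90 both. The Mantel-Haenszel odds ratio over deciles of region width was 2.88 (95% interval 2.12 to 3.93, Mantel-Haenszel chi-square p = 4.26e-12). By the same chi-square test it fell to 1.69 (p = 0.0871) without H3K27ac replicate 2, to 1.76 (p = 0.0586) without H3K27ac replicate 3, to 1.23 (p = 5.65e-05) without POU4F1 replicate 1, and to 1.21 (p = 0.992) for regions called in every library of each target. Regions are not independent replicates, and these p-values treat them as if they were.

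The shared regions with the strongest peaks lay at distances from 0.566 to 435 kb from the nearest gene end. By the mean percentile of the best peak over the 6 factor libraries, the leading region was on chromosome 11 at 88160791 to 88162535 (mm10) inside Cuedc1, at 4.88%. It was followed by a region on chromosome 15 at 25283679 to 25285530, 78.7 kb from an end of Basp1, which encodes a growth cone protein, and by a region on chromosome 14 at 120476940 to 120478345, 0.818 kb from an end of Rap2a. The other 7 were nearest to an end of Cic (13.2 kb), Bod1 (17.8 kb), Ppm1b (0.566 kb), Tle3 (1.27 kb), Peli2 (46.5 kb), Zfp608 (435 kb) and Il12a (25.8 kb), and those of Cic, Ppm1b and Tle3 overlapped the gene. Of these 10 regions, 9 had peaks in all 4 ISL1 libraries and 9 had an H3K27ac peak in at least 1 library. The 5 leading regions of the ISL1 only class were nearest to Pirt, Pip4k2b, Pcbd1, Elavl4 and Adamts16, and all had H3K27ac peaks in 2 libraries. The first 4 of them also carried a peak of POU4F1 replicate 1 and none of POU4F1 replicate 2. The 5 leading regions of the POU4F1 only class were nearest to Mta2, Hrh1, Gzf1, Bmt2 and Rps6kc1, and 3 of them had no peak in any ISL1 library.

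Pou4f1 carried clustered ISL1 regions, and Isl1 carried no replicated ISL1 region. Within 10 kb of Pou4f1 (chromosome 14, 104461675 to 104468118), 7 replicated ISL1 regions were found, 2 of them in all 4 libraries, at 104468238 to 104471370 and at 104472846 to 104475226, both outside the gene and each with H3K27ac peaks in 2 libraries. POU4F1 replicate 1 had 4 peaks at Pou4f1, the best at 104473844 to 104474548 inside the second of these regions, and POU4F1 replicate 2 had 0. The best peak of H3K27me3 replicate 2, at 104468396 to 104475052, overlapped both ISL1 regions found in all 4 libraries. So did the best peak of the library labelled H3K4me3 replicate 1 (104466649 to 104475065). At Isl1 (chromosome 13, 116298270 to 116309688), 3 ISL1 libraries had a peak, none at a position shared with another, and POU4F1 replicate 1 had 2 peaks. H3K27ac was present at an end of both genes in all 3 libraries. H3K27me3 was present there in 3 libraries at Isl1 and in 2 at Pou4f1.

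Shared regions carried H3K27ac most often and POU4F1 only regions least often. H3K27ac overlapped 77 of 101 shared regions (76.2%, 95% Wilson interval 67.1 to 83.5), 9626 of 20310 ISL1 only regions (47.4%, 46.7 to 48.1) and 109 of 444 POU4F1 only regions (24.5%, 20.8 to 28.8). Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over 9 comparisons, gave odds ratios of 3.56 for shared against ISL1 only (p = 1.48e-08), 9.86 for shared against POU4F1 only (p = 2.22e-21) and 2.77 for ISL1 only against POU4F1 only (p = 1.23e-21). Each of the 3 H3K27ac libraries showed the same order, though in H3K27ac replicate 1 the single-factor classes were nearly equal (7.03% and 6.76%). The last comparison was lost without H3K27ac replicate 2 (odds ratio 1.13, exact p = 0.664) or replicate 3 (1.09, exact p = 0.81), and was 13.9 without POU4F1 replicate 1 and 5.80 without POU4F1 replicate 2. The first was 2.00 without POU4F1 replicate 1, and the second ranged from 4.30 and 4.46 without H3K27ac replicates 2 and 3 to 14.9 without ISL1_70 replicate 2, 16.0 without POU4F1 replicate 2 and 27.8 without POU4F1 replicate 1. With regions called in every library of a target no comparison passed (adjusted exact p = 0.242, 0.518 and 0.229), and the last turned to an odds ratio of 0.674. Of the 545 POU4F1 regions present in both libraries, 372 were expected from shifts alone, so an unknown share of the POU4F1 only class is chance overlap of 2 lists rather than POU4F1 binding. Shared regions were wider, with a median of 1450 bp against 883 and 718.5 bp, which raises their chance of any overlap.

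H3K4me3 followed at lower shares and H3K27me3 did not differ by the test. Replicated H3K4me3 overlapped 8.91% of shared, 3.26% of ISL1 only and 2.70% of POU4F1 only regions, with odds ratios of 2.90 (adjusted p = 0.0136) and 3.52 (adjusted p = 0.0136) for shared regions against the others by Fisher's exact test. That set requires the library labelled H3K4me3 replicate 1, which resembles H3K27me3, and both calls were lost without ISL1_26 replicate 1 (odds ratios 1.84 and 1.85), without ISL1_70 replicate 2 (2.65 and 2.29) and without H3K4me3 replicate 2 (1.86 and 1.97). The second was also lost without ISL1_70 replicate 1 (3.15) and was 15.4 without POU4F1 replicate 1, and the first was 1.44 without POU4F1 replicate 2. Without the library labelled H3K4me3 replicate 1 they were 4.64 and 7.01. In H3K4me3 replicate 2 by itself the shares were 39.6%, 12.4% and 8.56%. Replicated H3K27me3 overlapped 10.9% of shared, 6.92% of ISL1 only and 6.76% of POU4F1 only regions, and none of its 3 comparisons passed the exact test (adjusted p = 0.174, 0.266 and 1). They passed without POU4F1 replicate 1, with odds ratios of 2.02, 6.32 and 3.13, and the last of them and shared against POU4F1 only passed without POU4F1 replicate 2 (1.98 and 1.89); shared against POU4F1 only also passed without H3K27me3 replicate 3 (3.10). H3K4me3 between the single-factor classes (odds ratio 1.21, adjusted exact p = 0.663) passed without POU4F1 replicate 1 (5.65), POU4F1 replicate 2 (2.53) or the library labelled H3K4me3 replicate 1 (1.51). In H3K27me3 replicates 1 to 3 taken singly, 25.7%, 11.9% and 13.9% of shared regions were covered. The shares were 9.25%, 6.73% and 8.61% of ISL1 only and 6.08%, 6.31% and 8.78% of POU4F1 only regions.

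**Figure D3:**
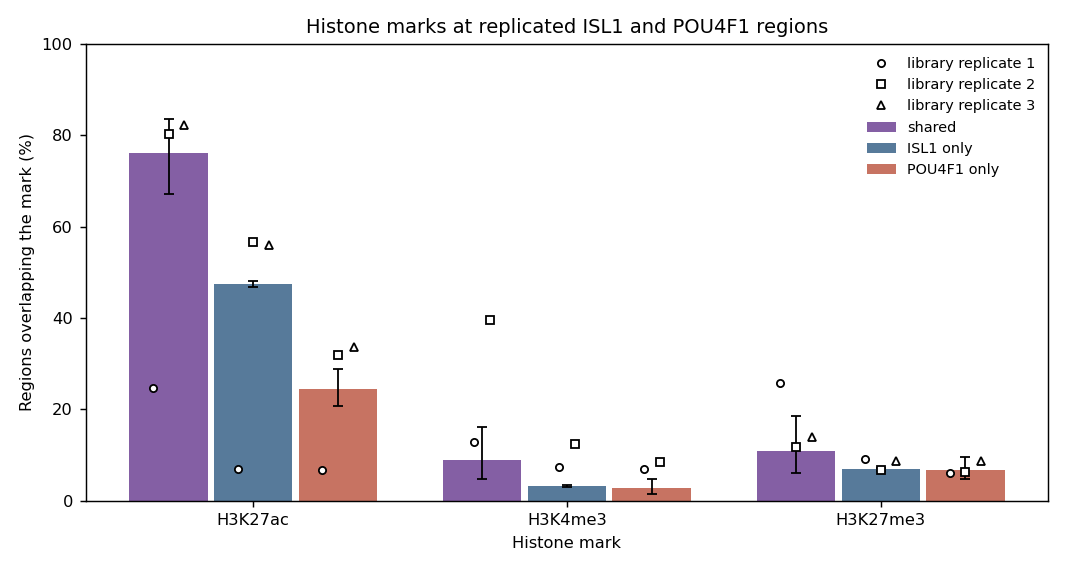
Share of shared (101), ISL1 only (20310) and POU4F1 only (444) regions that overlap each histone mark (%): bars for replicated mark regions with 95% Wilson intervals, points for single mark libraries. H3K27ac covers 76.2%, 47.4% and 24.5% of the classes, and the H3K4me3 bars (8.91% for shared regions) lie far below the H3K4me3 replicate 2 points (39.6%).

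Replicated shared regions lay at gene ends more often than ISL1 only or POU4F1 only regions. This did not hold among the 10000 best peaks of each library (odds ratios 1.31 against ISL1 only and 0.694 against POU4F1 only). Within 1 kb of an annotated gene end were 37 of 101 shared regions (36.6%), 14.7% of ISL1 only and 14.2% of POU4F1 only regions. Fisher's exact test, two-sided, gave odds ratios of 3.36 (p = 4.79e-08) against ISL1 only and 3.5 (p = 1.27e-06) against POU4F1 only for shared regions, and 1.04 (p = 0.839) between the single-factor classes. When shared regions were defined with POU4F1 replicate 1 alone, the excess over ISL1 only regions ended (odds ratio 1.07, exact p = 0.226). Against POU4F1 only the odds ratio was 8.72 without POU4F1 replicate 1, 2.17 without ISL1_26 replicate 1 and 2.22 without ISL1_70 replicate 1, and between the single-factor classes the odds ratio was 3.09 and 2.44 without POU4F1 replicate 1 and 2 and 0.722 without ISL1_70 replicate 1. Most single-factor regions lay inside genes (44.5% and 39.6%) or outside them (40.8% and 46.2%).

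Genes fell into an H3K27ac set, an H3K27me3 set and a smaller set with both marks. Of 21887 protein-coding genes, 8645 had H3K27ac without H3K27me3 within 1 kb of an end, 2732 had H3K27me3 without H3K27ac, 1760 had both and 8750 neither. ISL1 regions lay at the ends of 25.6% of the H3K27ac genes and 11.9% of the H3K27me3 genes (Fisher's exact test, odds ratio 2.53, p = 2.62e-55), of 28.6% of genes with both marks and of 3.45% of genes with neither. By single library the direction was not uniform. Peaks of ISL1_26 replicate 1 lay at 45.3% of H3K27ac and 31.7% of H3K27me3 genes. For ISL1_70 replicate 1 the shares were 47.8% and 26.6%, and for replicate 3 they were 18.2% and 14.2%. In ISL1_70 replicate 2 they were reversed, at 12.6% and 18.7%. POU4F1 regions were at 71 of the H3K27ac genes and 10 of the H3K27me3 genes (exact test, odds ratio 2.25, p = 0.0126), and shared regions at 36 and 3 (odds ratio 3.80, p = 0.0139). The last comparisons rest on few genes: within 5 kb the odds ratios were 0.980 (exact p = 0.922) for POU4F1 and 0.840 (exact p = 0.615) for shared regions. The shared call was lost without ISL1_26 replicate 1 (6.02), ISL1_70 replicate 1 (3.01), ISL1_70 replicate 3 (2.85), H3K27me3 replicate 2 (2.86) or H3K27me3 replicate 3 (2.68), and the POU4F1 call without H3K27me3 replicate 2 (2.39) or 3 (2.27), with 1.46 and 1.35 without POU4F1 replicate 1 and 2. H3K27ac genes numbered 3978 and 4193 without H3K27ac replicates 2 and 3, H3K27me3 genes 1461 and 1387 without H3K27me3 replicates 2 and 3, and genes with both marks 579, 616, 930 and 820 in these settings.

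Inner ear neuron transcription factors and axon guidance genes carried ISL1 regions more often than random genes of the same length. An ISL1 region lay in the gene or within 10 kb of it in 27 of 31 inner ear neuron transcription factors against 14.5 ± 2.48 (SD) in 10000 matched random lists (one-sided permutation test, adjusted p = 0.0012 over 12 lists). Among them were Runx1, with 11 regions, Ebf2, with 11, Ebf1, with 21, and Ebf3, with 13, all with peaks in 4 ISL1 libraries. Counted library by library, the transcription factors lay above the random lists in 4 of 4 ISL1 libraries, 3 of them past the threshold, and the axon guidance genes in 4 of 4, 0 of them past it. Cytoskeleton and synapse genes did so in 4 of 4, 1 of them past it, and housekeeping genes in 4 of 4, 0 of them past it. Axon guidance and adhesion genes followed with 28 of 30 (expected 21.9, adjusted permutation p = 0.0216), among them Unc5c, a netrin receptor, Ephb2, Nrp2, a semaphorin receptor, and Efna5. Neuronal cytoskeleton and synapse genes reached 22 of 30 (expected 15.8, adjusted permutation p = 0.0288), with Gap43, Cacna2d1, Celf4 and Map1b leading, and housekeeping genes 12 of 20 (expected 6.46, adjusted p = 0.0288). When random lists were also matched on H3K27ac at a gene end, the transcription factors (adjusted permutation p = 0.0012) and the axon guidance genes (adjusted p = 0.0276) still passed, and the cytoskeleton (0.192) and housekeeping (0.197) lists did not. The counts of these 4 lists were then 1.672, 1.263, 1.265 and 1.421 times the expected ones, in this order. Without ISL1_26 replicate 1 only the transcription factors passed. Without ISL1_70 replicate 3 the cytoskeleton list (adjusted permutation p = 0.0759) was lost, and the housekeeping list was lost without any 1 of the 4 ISL1 libraries.

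The other lists did not pass for replicated ISL1 regions. In ISL1_70 replicate 2 by itself, however, otic markers (16 of 20, adjusted permutation p = 0.0015), mesenchyme markers (11 of 15, 0.0316), muscle, heart, gut and liver regulators (16 of 20, 0.0012) and Hox genes (16 of 20, 0.0006) passed, and in ISL1_26 replicate 1 by itself cell cycle genes did (20 of 20, 0.0048). ISL1_70 replicate 2 also overlapped H3K27me3 replicate 2 at 5.42 times the shifted level. The ratio was 2.60 for ISL1_26 replicate 1, and 2.64 and 2.36 for ISL1_70 replicates 1 and 3. Peaks of ISL1_70 replicate 2 lay at the ends of 18.7% of H3K27me3 genes and 12.6% of H3K27ac genes. Whether its list calls reflect ISL1 binding was not tested. Neurotrophin and survival genes, named in the title's question, had an ISL1 region in 16 of 25 members (expected 12.3, adjusted permutation p = 0.167), and the count passed without ISL1_70 replicate 1 (adjusted p = 0.0252). It also passed with the 10000 best peaks of each library, with regions in every ISL1 library, with the nearest gene end within 50 kb and within 5 kb of a gene end. Their leading members were Gfra1, with 11 regions, Bcl2l1, an inhibitor of apoptosis, with 3, Ntrk2, the BDNF receptor, with 8, and Gfra2, with 4. Ntrk3, the neurotrophin-3 receptor, had a region in all 4 libraries on chromosome 7 at 78576809 to 78579021, inside the gene and 3120 bp from an end. It was chosen after its values were seen. Markers of other cell types stood at 4 of 15 for Schwann cells and neural crest (adjusted permutation p = 0.806), 8 of 20 for otic epithelium and hair cells (0.640), 9 of 15 for mesenchyme (0.167) and 5 of 15 for endothelium and blood (0.806). Muscle, heart, gut and liver regulators had 9 of 20 (0.454), Hox genes 7 of 20 (0.454) and cell cycle genes 10 of 20 (0.110). The cell cycle list passed with a −log10 q of at least 5, with regions linked to the nearest gene end within 50 kb and with regions within 5 kb of a gene end.

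Regions shared with POU4F1 were too few for these lists, and with POU4F1 replicate 1 alone 3 neuronal lists passed. A replicated shared region was found for 1 member of any list, the axon guidance gene Slit1 (chromosome 19, 41597824 to 41747275), and 0 of 12 lists passed the permutation test, with 0 lists at an unadjusted p under 0.05. Peaks of POU4F1 replicate 1 on a replicated ISL1 region, counted after the data were examined, lay at 16 of 31 inner ear neuron transcription factors against 4.04 ± 1.74 expected (adjusted permutation p = 0.0012), 16 of 30 axon guidance genes against 8.28 ± 2.32 (adjusted p = 0.006) and 11 of 30 cytoskeleton and synapse genes against 4.42 ± 1.84 (adjusted p = 0.006). The transcription factors included Pou4f1, Gata3, Nhlh1, Runx1, Runx3, Prox1, Casz1 and Ebf1 to Ebf3, the axon guidance genes Robo1, Robo2, Slit1 and Nrp2, and the last list Nefl, Elavl3, Elavl4 and the sodium channel gene Scn9a. The 3 lists also passed when random lists were matched on H3K27ac (adjusted permutation p = 0.0012, 0.0096 and 0.0256). Neurotrophin and survival genes stood at 3 of 25 (Ntrk2, Gfra1 and Bcl2l1, expected 3.20), and otic and hair cell markers at 3 of 20 (1.43). Schwann cell, endothelial, Hox and cell cycle genes stood at 0, with 0.82, 1.12, 0.85 and 0.91 expected. Mesenchyme markers (expected 1.35), muscle, heart, gut and liver regulators (1.45) and housekeeping genes (1.05) had 1 each. With so few expected, these low counts do not show that the lists lack such peaks. ISL1 regions by themselves were enriched at the 3 lists that passed, so their counts do not separate POU4F1 from ISL1. Peaks of POU4F1 replicate 1 anywhere lay at 29 of 31 transcription factors (expected 17.6, adjusted permutation p = 0.0012), 26 of 30 cytoskeleton and synapse genes (19.5, 0.0186) and 15 of 20 otic and hair cell markers (9.57, 0.028), and did not pass for axon guidance genes (28 of 30, 26.3, 0.466). Peaks of POU4F1 replicate 2 anywhere passed for none of the 12 lists. Peaks of POU4F1 replicate 2 on replicated ISL1 regions passed for none of the neuronal lists, while the otic epithelium and hair cell list did (4 of 20, 6.78 times the expected count, adjusted permutation p = 0.0336).

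H3K27ac passed for 4 of the 12 lists, 2 of them neuronal, and H3K27me3 for 10 of the 12. H3K27ac lay at an end of 23 of 31 inner ear neuron transcription factors (expected 15.3, adjusted permutation p = 0.0087), among them Neurog1, Neurod1, Isl1 and Pou4f1, of 24 of 30 cytoskeleton and synapse genes (16.0, adjusted p = 0.0087), of 17 of 20 cell cycle and progenitor genes (8.87, adjusted p = 0.0024) and of 18 of 20 housekeeping genes (9.87, adjusted p = 0.0024). Each of these 4 lists lay above its random lists in 3 of 3 H3K27ac libraries, but past the threshold in 1 of 3 for the transcription factors, 2 of 3 for the cytoskeleton list and 3 of 3 for the other lists. Over all alternatives run, the H3K27ac call of the transcription factors was lost in 1. H3K27ac lay at 18 of 25 neurotrophin and survival genes (adjusted permutation p = 0.117) and 18 of 30 axon guidance genes (0.619), the latter passing without H3K27ac replicate 2 (0.0012) or 3 (0.0032). Only 2 of 20 muscle, heart, gut and liver regulators had it (expected 10.1), fewer than in random lists (one-sided permutation test for fewer, adjusted p = 0.0036). Schwann cell and neural crest markers had 5 of 15, among them Sox10 and Erbb3, otic markers 9 of 20, mesenchyme markers 5 of 15, endothelial and blood markers 4 of 15 and Hox genes 4 of 20, none past either threshold.

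H3K27me3 lay at 20 of 20 Hox genes (expected 4.25), 13 of 15 mesenchyme markers (3.40), 16 of 20 otic and hair cell markers (4.32), 16 of 20 muscle, heart, gut and liver regulators (4.33) and 22 of 31 inner ear neuron transcription factors (8.32), each with an adjusted p of 0.00024, the smallest the permutation test gave. It also passed for cytoskeleton and synapse genes (17 of 30, adjusted permutation p = 0.001), Schwann cell and neural crest markers (9 of 15, 0.00154), axon guidance genes (17 of 30, 0.0231), neurotrophin and survival genes (11 of 25, 0.0348) and cell cycle genes (8 of 20, 0.0358). By single library, the transcription factor, mesenchyme, cytoskeleton and cell cycle lists passed in 2 of 3 H3K27me3 libraries and the neurotrophin list in 1. The remaining lists that passed did so in 3 of 3. The neurotrophin call was lost without H3K27me3 replicate 2 (adjusted permutation p = 0.23). Over all alternatives run, the neurotrophin call was lost in 2 and the axon guidance call in 1. H3K27me3 did not pass for endothelial and blood markers (5 of 15, adjusted permutation p = 0.164, and 0.0488 without H3K27me3 replicate 3), and 0 of 20 housekeeping genes had it. In replicated regions over the gene and 5 kb each side, H3K27me3 covered 56.2 kb of Tbx5 and 37.3 kb of Pax7, regulators of heart and limb and of muscle, 52.7 kb of Hoxa3, 45.3 kb of Hoxd3, 50.5 kb of Pax2, an otic regulator, 32.5 kb of Tbx15 and 16.6 kb of Tbx1. Among members of the neuronal lists with H3K27me3 at an end in all 3 libraries, long coverage was found at Lhx1 (14.7 kb), Neurod2 (13.9 kb), Celf4 (21.3 kb), Nefh (9.37 kb), Gdnf (13.4 kb) and Unc5b (11.1 kb). Runx3 (34.3 kb) and Casz1 (24.8 kb) were covered further, with a peak at an end in 1 and 2 libraries. Outside the lists, Nfix (99.3 kb), Cdh22 (63.2 kb), Prdm16 (50.6 kb), Hoxb3 (49.7 kb) and Gm37013 (46.9 kb) were covered furthest.

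**Figure D4:**
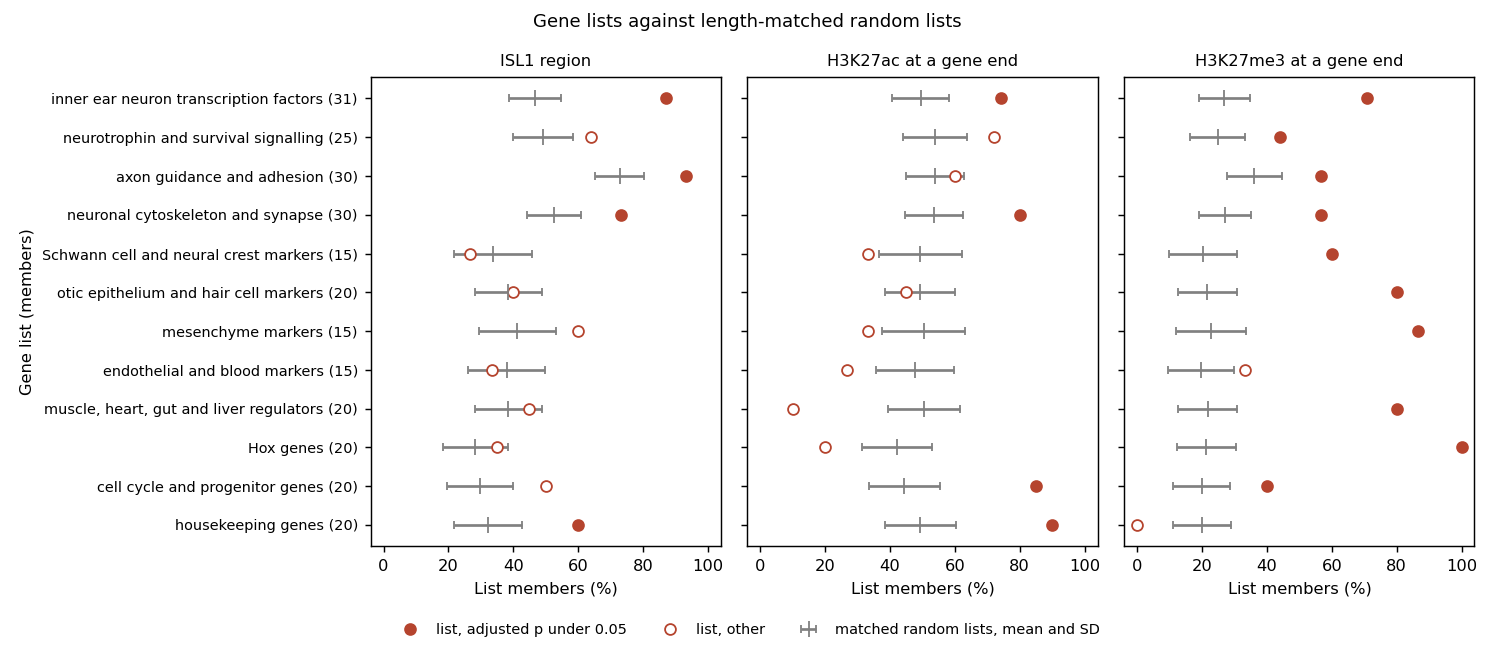
Share of each list's members (%) with an ISL1 region in the gene or within 10 kb, or with H3K27ac or H3K27me3 within 1 kb of a gene end; circles are the lists (filled where the adjusted p is under 0.05) and grey marks the mean and SD of 10000 random lists matched on gene length. Hox genes lie at 100% for H3K27me3 and 20% for H3K27ac, housekeeping genes at 0% and 90%, and inner ear neuron transcription factors above their random lists in all 3 panels.

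Of 102 genes with a shared region, 96 had 1 and none had more than 2. Gm13275, Gm13279, Gm13285 and Gm13287 had 2 each. They lie together on chromosome 4 between 88793742 and 88803802, so that the 10 kb margins let them share the same regions. Gm40365 on chromosome 6 (47669367 to 47675070) also had 2. Whether reads at these predicted genes are shared with similar copies was not tested, and their peaks are uncertain.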

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

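No explanation was tested for the values here, which were counted because they lie in data that no comparison used, and no IgG list was analysed here to set a background for them. Over the 14 lists, 913 peaks lay on sequences other than chromosomes 1 to 19, X and Y, from 3 in H3K27me3 replicate 1 to 193 in POU4F1 replicate 2. Of them, 16 lay on the mitochondrial chromosome: 5 in POU4F1 replicate 2, 4 in H3K27ac replicate 1, 2 each in POU4F1 replicate 1 and ISL1_70 replicate 1, 1 in each of the other ISL1 libraries, and 0 in the H3K4me3 and H3K27me3 lists.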

How the results depend on the processing

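The settings without 3 libraries together and without regions called in 12 or more libraries were chosen after the data were examined; the others were planned. Of the alternatives for the results that answer a comparison, 512 left direction and call or count as they were, 47 moved a count, 36 ended a call, 20 made one and 6 turned a direction. Results of single gene lists were counted apart: 964 stayed as they were, 19 ended a call, 17 made one and 8 turned a direction. The excess of ISL1-POU4F1 overlap over shifts held in every alternative run, from 2.07 times (regions of any library) to 54.4 times (13 regions among the 10000 best peaks of each library), and was 18.6 with an overlap of 50% and 26.3 with summit windows. All 91 library pairs exceeded their shifts whatever the targets, so the direction of this excess does not set ISL1 and POU4F1 apart. The causes of the changes below were not tested, apart from the smaller number of regions or libraries that a setting leaves. Depth is unknown for every list. The planned motif test and its alternatives were not run.

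With a −log10 q of at least 5, H3K4me3 at shared regions had odds ratios of 1.78 against ISL1 only and 1.86 against POU4F1 only, and POU4F1 at the ends of H3K27ac against H3K27me3 genes had 1.90. With the 10000 best peaks of each library, replicated regions numbered 4508 (ISL1), 66 (POU4F1), 1037 (H3K4me3), 7074 (H3K27me3) and 7353 (H3K27ac). The H3K4me3 odds ratios were then 2.26 and 1.30, that of H3K27ac between the single-factor classes 2.35, those for shared regions near a gene end 1.31 against ISL1 only and 0.694 against POU4F1 only, and that of shared regions at H3K27ac genes 2.28. H3K27ac genes numbered 4450, genes with both marks 368, and housekeeping genes with an ISL1 region 0 of 20 (10000 best peaks of each library).

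With regions of any library, counts were 214116 (ISL1), 62799 (POU4F1), 35862 (H3K4me3), 52503 (H3K27me3) and 220803 (H3K27ac). Odds ratios that did not pass with replicated regions and passed here were 1.80 for H3K4me3 and 1.54 for H3K27me3 between the single-factor classes, 2.42 and 3.71 for H3K27me3 at shared regions, and 1.47 for gene ends between the single-factor classes. Genes with both marks numbered 7885. For peaks of any library, 2 lists passed for shared regions, with inner ear neuron transcription factors at 2.37 times the expected count, and 0 lists passed for ISL1 regions. With regions in every library, 1547 ISL1, 3251 H3K27me3 and 4720 H3K27ac regions were left, and the association within H3K27ac regions was 1.21. For H3K4me3 the odds ratios of shared regions were 1.77 and 1.20, for H3K27ac 2.75 and 1.85, and between the single-factor classes 0.674 for H3K27ac and 0.533 for gene ends. For peaks in every library of the target, H3K27ac genes numbered 4244, genes with both marks 299, the odds ratio of shared regions at H3K27ac genes was 4.28, 2 lists passed for ISL1 regions, and 0 of 20 housekeeping genes had an ISL1 region.

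Within 5 kb of a gene end, genes with both marks numbered 3145, and the odds ratios at H3K27ac genes were 0.980 for POU4F1 and 0.840 for shared regions. Without POU4F1 replicate 2, the library labelled H3K4me3 replicate 1 and H3K27me3 replicate 1, POU4F1 had 34249 regions and H3K4me3 22425. Odds ratios between the single-factor classes were 4.21 for H3K4me3, 1.96 for H3K27me3 and 2.44 for gene ends, those of shared regions were 1.71 for H3K27me3 against POU4F1 only and 1.07 for gene ends against ISL1 only, and 3 lists passed for shared regions (3 doubtful libraries left out together), with 3.93 times the expected count for inner ear neuron transcription factors and 2.48 times for the cytoskeleton and synapse list. Without regions called in 12 or more libraries, the H3K4me3 odds ratios of shared regions were 1.57 and 1.83.

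Leaving out each library in turn gave 8418 to 20413 ISL1, 545 to 34249 POU4F1, 2039 to 22425 H3K4me3, 3440 to 11078 H3K27me3 and 5044 to 49941 H3K27ac regions. The association within H3K27ac regions ranged from 1.23 to 2.96 and the overlap from 2.13 to 19.2 times. For shared against ISL1 only, shared against POU4F1 only and the single-factor classes, odds ratios ranged from 1.44 to 4.64, 1.85 to 15.4 and 0.863 to 5.65 for H3K4me3, from 2.00 to 5.03, 4.30 to 27.8 and 1.09 to 13.9 for H3K27ac, from 0.953 to 2.17, 1.14 to 6.32 and 0.785 to 3.13 for H3K27me3, and from 1.07 to 3.82, 2.17 to 8.72 and 0.722 to 3.09 for gene ends. H3K27ac genes ranged from 3978 to 9585, H3K27me3 genes from 1387 to 3913 and genes with both marks from 579 to 1760. At H3K27ac against H3K27me3 genes the odds ratios ranged from 1.86 to 3.26 for ISL1, 1.35 to 2.87 for POU4F1 and 2.68 to 6.02 for shared regions. In leave-one-out settings, lists past the threshold numbered 0 to 3 for shared regions, 1 to 4 for ISL1 regions, 4 to 5 for H3K27ac and 9 to 11 for H3K27me3; the shared-region count over the expected one reached 6.78 for the otic list without POU4F1 replicate 1.

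The numbers of the replicates were used as a replicate block for the overlap of single ISL1_70 and POU4F1 libraries. The 2 pairs with the same number shared 4248 peaks, 3.11 times the shifted number, and the 4 pairs with different numbers 5403, 2.43 times. With 2 such pairs and no label that ties a number to a shared day or animal, the numbers were not taken to pair the samples.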

Other observations

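Several neuronal regulators carried H3K27ac and H3K27me3 at their ends at once, about as many as the 2 marks taken singly would give. Both marks lay at an end of 17 of 31 inner ear neuron transcription factors against 3.30 ± 1.68 (SD) in length-matched random lists, 5.15 times as many (one-sided permutation test, adjusted p = 0.0006 over 12 lists), with Neurod1, Isl1, Pou4f1 and Nhlh1 among them. The same held for 13 of 30 cytoskeleton and synapse genes (expected 3.35, adjusted permutation p = 0.0006), such as Tubb3, Nefl, Prph and Stmn2, for 7 of 20 cell cycle and progenitor genes (1.44, adjusted p = 0.0024), such as Notch1, Dll1 and Hes1, for 6 of 20 otic and hair cell markers (1.71, adjusted p = 0.0144), such as Atoh1 and Pou4f3, and for 7 of 25 neurotrophin and survival genes (2.51, adjusted p = 0.023), such as Ntrk2 and Ret. It held for 7 of 30 axon guidance genes (adjusted permutation p = 0.218), 4 of 15 Schwann cell and neural crest markers (0.0518), 4 of 15 mesenchyme markers (0.0631), 4 of 20 Hox genes (0.0756), 1 of 15 endothelial markers (0.860), and 0 of 20 in both the muscle, heart, gut and liver and the housekeeping lists. The shares of a list with each mark alone would give 16.3 of the transcription factors, 13.6 of the cytoskeleton and synapse genes, 6.8 of the cell cycle genes, 7.2 of the otic markers and 7.92 of the neurotrophin and survival genes, so the excess over random lists shows no further co-occurrence of the marks. The count of transcription factors was 11 without H3K27ac replicate 2 or 3 and 8 without H3K27me3 replicate 2, and that of cell cycle genes 4 without H3K27ac replicate 3, still past the threshold. The otic list was lost without H3K27ac replicate 2 (1 of 20) or 3 (1 of 20), and the neurotrophin list without H3K27ac replicate 2 (0 of 25), H3K27ac replicate 3 (2 of 25) or H3K27me3 replicate 2 (4 of 25). Other lists passed in some leave-outs. Schwann cell and mesenchyme markers did so without any 1 H3K27me3 library, and Schwann cell markers also without H3K27ac replicate 1. Axon guidance genes passed without H3K27me3 replicate 3 or H3K27ac replicate 2 or 3, and Hox genes without H3K27me3 replicate 3. The marks can lie at opposite ends of a gene, and 15 of the 17 transcription factors had both at the same end. The genes were counted after the data were examined, and the peak lists do not tell whether both marks lie in the same cells.

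All tests below were chosen after the patterns were seen, and only the test of POU4F1 replicate 1 against histone libraries was set out before its result. The library labelled H3K4me3 replicate 1 resembled H3K27me3. A wrong label for this library stays open, since its Jaccard indices (the lower with H3K27me3 replicates 2 and 3 was 0.496, that with H3K4me3 replicate 2 was 0.036) are the resemblance itself and cannot test it. Its peaks lay at 97.1% of 1219 gene ends in H3K27me3 and 1.26% of 8332 in H3K27ac. For H3K4me3 replicate 2 the shares were 13.4% and 71.9%. These gene ends were set partly by H3K27me3 replicates 2 and 3, so the shares describe the same resemblance. By its peaks the list is like H3K27me3, and the lists do not tell how its label arose. H3K4me3 at Polycomb-marked genes is argued against, since 0 of 20 housekeeping genes had a peak. A swap with H3K27me3 replicate 1 stays open, since the values go both ways: it overlapped H3K4me3 replicate 2 at 22.0 times the shifted level and H3K27me3 replicates 2 and 3 at 15.5 and 12.4 times, but among 1219 gene ends in H3K27me3 and 8332 in H3K27ac, H3K27me3 replicate 1 had peaks at 43.2% and 40.9%, a ratio of 1.06, while H3K4me3 replicate 2 had a ratio of 0.186. By Jaccard index, H3K27me3 replicate 1 was closest to H3K27me3 replicate 2 (0.0811), with 0.0773 for H3K4me3 replicate 2. Its list also lay near the calling threshold (median −log10 q of 1.09). A wrong antibody, a swap with a library outside the series and a mixed H3K27me3 replicate 1 stay open, and no other biological explanation was tested.

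The POU4F1 libraries shared few peaks. Among peaks with a −log10 q of at least 5 the share was 1.85%, no higher than the 1.87% of all peaks. This cutoff could change little, since the median −log10 q was 64.8 in POU4F1 replicate 1 and 22.6 in replicate 2. Among the 10000 best peaks of each library the share was 0.66%, but shares fall as lists shorten. Over the shifted level the overlap was 1.46, 1.51 and 1.83 in these settings, from all peaks to the best. The low sharing was therefore not confined to peaks near the calling threshold, and whether weak peaks add to it stays open. A list made mostly of background in POU4F1 replicate 2 may account for it: the 7274 strongest of its 29096 peaks lay on H3K27ac regions 2.50 times as often as after shifts, against 5.71 to 9.64 times for the same share of peaks in the other 5 factor libraries. Within H3K27ac regions, in strata of width and H3K27ac strength, the odds ratio between the 2 POU4F1 libraries was 1.10 (95% interval 0.969 to 1.24). Whether the libraries differ in depth, control or tissue stays open.

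ISL1 and POU4F1 overlapped more than shifted positions did. H3K27ac chromatin alone as the whole cause was tested in 25 strata of width and H3K27ac strength. The odds ratio was 2.55 (lower 95% bound 1.86), and the interval stayed above 1 without each ISL1, POU4F1 or H3K27ac library. It was 2.44 (2.29 to 2.61) without POU4F1 replicate 2 and 1.15 (1.04 to 1.28) without POU4F1 replicate 1. Without H3K27ac replicate 2 it was 1.90 (1.07 to 3.38), and without H3K27ac replicate 3 it was 1.79 (1.03 to 3.13, Mantel-Haenszel chi-square p = 0.0528). For peaks in every library of the target it was 1.26 (0.384 to 4.11), with 3 regions of both factors, too few to decide. Width and H3K27ac strength in these strata thus did not remove the association, which came mainly from POU4F1 replicate 1. The strata are coarse, so H3K27ac differences within a stratum stay open as a cause. The intervals also treat regions as independent. Accessible chromatin that attracts any antibody stays open, since peaks of H3K4me3 and H3K27me3 libraries follow those marks and cannot stand in for open chromatin. The odds ratios of POU4F1 replicate 1 with the 4 ISL1 libraries were 1.73 to 2.20. Its highest with an H3K4me3 or H3K27me3 library was 1.41 (95% interval 1.25 to 1.58), so its peaks went with ISL1 more than with these marks. For POU4F1 replicate 2 the order was the opposite, with 1.05 to 1.20 for the ISL1 libraries and 1.34 to 1.58 for these histone libraries. Its 95% intervals held 1 with ISL1_26 replicate 1 (0.962 to 1.16) and with ISL1_70 replicates 1 (0.9485 to 1.15) and 2 (0.917 to 1.19). With ISL1_70 replicate 3 the interval did not hold 1 (1.07 to 1.34). The opposite order was seen after that test was set. Shared binding of ISL1 and POU4F1 is a hypothesis that these values leave open, with IgG lists and an independent map of open chromatin not analysed here, and direct contact of the proteins cannot be read from peak positions.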
